A study of Rattus norvegicus with 96 samples.

How the data were processed

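RNA from the livers of 96 male rats was measured, 1 array per animal, in 20 groups that were taken from the labels: 16 treated groups and 4 vehicle groups of 4 or 5 animals. Per the labels' protocols, dosing was by daily oral gavage for 5 days, livers were taken 24 h after the last dose, and total RNA was labelled for whole-transcript rat arrays. Per the submitters' notes, processing used Affymetrix Expression Console 1.1. Some further arrays failed quality control per the study design. Which ones, and other steps before deposit, are not given. Deposited values are linear intensities from 6e-06 to 38140.9, 5.28% of them below 1. There are 36685 probe sets. Of these, 14824 carry 1 gene symbol, 829 carry several and 21032 are not listed in the annotation used, and 14670 of the single-symbol probe sets matched the current gene table by gene number. Histopathology was not used here.

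From these values log2(intensity + 16) was computed. The design written before the data were examined said that a log2 would be taken of linear values; the offset of 16 was set once the values were seen to be linear, and offsets of 1 and 32 were tried. The probe set with the highest mean stood for each of 14557 symbols, 234 of which had more than 1 probe set. A gene was tested where it reached the median of all probe sets of the array on at least 4 arrays, which left 11234 genes. No further scaling was applied. Median intensities lay between 18.64 and 22.11 in the allyl alcohol exposure, 22.64 and 25.58 in that of bromobenzene, 20.22 and 23.12 in that of carbon tetrachloride and 17.34 and 23.42 in that of 4,4'-methylenedianiline and dexamethasone. Correlations between arrays lay between 0.8207 and 0.9829.

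Each treated group was compared with its own vehicle group by limma 3.58.1 in R 4.3.3, with the package data.table, version 1.17.8, in 1 fit per exposure with empirical Bayes moderation, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. A dose trend was a slope on mg/kg over the arrays of an exposure. The responses at the top doses were set against each other in 1 fit of all 96 arrays, for 10 pairs, and the vehicle groups were compared by an F test with 3 degrees of freedom. The tests between adjacent doses were added after the data were seen. Overlaps of lists of changed genes are given beside the number for independent lists, and the effect of the shared vehicle was estimated from 100 simulations.

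The 29 gene lists were written before the data were examined and hold 663 entries, of which 471 were tested; 3 of these name a gene already in the same list, which was counted once, leaving 468. They cover extracellular matrix, stellate cell and myofibroblast, cholangiocyte, macrophage, neutrophil, lymphocyte, endothelial, mesothelial and erythroid markers, periportal and pericentral hepatocyte genes and hepatocyte secreted proteins. The others are NRF2 targets, glutathione transferases, cytochromes P450, bile acid synthesis and transport, proliferation, p53 targets, unfolded protein and amino acid stress, heat shock, acute phase, inflammatory and interferon-stimulated genes, cholesterol synthesis, fatty acid synthesis, PPAR alpha targets, glucocorticoid targets, amino acid and urea cycle enzymes, and circadian clock genes. Lists of at least 5 genes, 28 of the 29, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The mesothelial markers had 4 measured genes and were not tested as a list. After the data were seen, an exact permutation test on both sides of each list's mean per animal, relative to the median of the array, was added, since camera with a preset correlation also called lists in random regroupings; it was adjusted over the 28 lists, and with 4 or 5 animals per group no list can pass on its own, since at least 5 must have low p together. Lists of MHC class II, fetal liver and sex-dependent genes were added then too.

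The genes named follow a rule set before the data were examined: at each top dose the 6 largest rises and 6 largest falls among genes past the threshold whose treated animals all lie beyond all vehicle animals, at each lower dose the 3 largest of each, in each list called the 2 members with the largest change in the direction of the call and 1 the other way, per pair of responses the 2 with the largest difference each way, and the 4 with the smallest p between vehicle groups. LOC100360095 was not named, though it passed the threshold at the top doses of allyl alcohol, bromobenzene, carbon tetrachloride and 4,4'-methylenedianiline. Its changes there were -7.01, -8.37, -1.6 and -6.03, and the falls ranked below leave it out. Col1a1, Krt7, Krt19, Timp1, Nqo1, Hmox1, Lcn2, Cyp7a1 and Tat were named in advance. Acta2, Mki67, Cdkn1a, Cyp2e1 and Glul, also named in advance, have no single-symbol probe set among the genes tested and are not analysed here.

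The alternatives were no filter, a floor at the 75th percentile (6659 genes), quantile normalization, array medians set equal, eBayes with trend and robust, array weights, the mean of a gene's probe sets, all probe sets, an adjusted p under 0.01, a minimum 2-fold change, all 96 arrays in 1 fit, the compared groups alone, the replicate number as a block, dose level in place of mg/kg, camera on ranks, Spearman's rho, and each animal left out in turn. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.

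The fits were tested on simulated data (200 of 11234 genes changed, random seed 20). For 1.5-fold, 2-fold and 4-fold changes, limma recovered 40.3%, 80.6% and 98.5% at the top dose of allyl alcohol, 47.8%, 92.5% and 98.5% at that of bromobenzene and 59.7%, 92.5% and 100% at that of carbon tetrachloride. At 162 mg/kg 4,4'-methylenedianiline the shares were 55.2%, 89.6% and 100%, and under dexamethasone 55.2%, 92.5% and 100%. The lowest doses gave 68.7%, 92.5% and 100% (carbon tetrachloride) and 61.2%, 91% and 100% (4,4'-methylenedianiline). Camera called 3 of 3 moved lists at each top dose and 0 or 1 of 25 others. Random regroupings gave medians of 5 to 8 lists. Few arrays limit precision.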

Results

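Livers were collected from male Sprague Dawley rats, an outbred laboratory stock, 24 h after the last of 5 daily oral doses of a liver toxicant or its vehicle, and total RNA was measured on whole-transcript arrays. The 96 arrays, each from a separate animal per the labels, fell into 20 groups. Allyl alcohol was given at 21 (n = 5), 27 (n = 4), 35 (n = 4) and 45 mg/kg (n = 4) with 5 vehicle animals. Bromobenzene was given at 124, 229, 424 and 785 mg/kg (n = 5 each) with 4 vehicle animals. Carbon tetrachloride was given at 20, 43, 93 and 200 mg/kg (n = 5 each) with 5 vehicle animals. 4,4'-Methylenedianiline was given at 22, 60 and 162 mg/kg and dexamethasone at 1 mg/kg (n = 5 each), and these share 5 vehicle animals. The series relates gene expression to the histopathology of toxic liver injury, not analysed here. Median intensities lay between 17.34 and 25.58, no 2 arrays held identical values, and 11234 of 14557 gene symbols were bright enough to be tested. The 4 or 5 arrays per group limit precision. Below, a change is a difference of log2(intensity + 16) between treated and vehicle animals with its SE. A level is that log2 value with its SD, and adjusted p is limma's by Benjamini-Hochberg over all genes tested. Variance is pooled over all groups of a fit, so spread at 1 dose enters SE and p at others. A fold, 2 raised to the size of a change, is a ratio of intensity + 16. It understates the ratio of intensities, most for dim genes, and also sets the minimum 2-fold change.

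**Figure D1:**
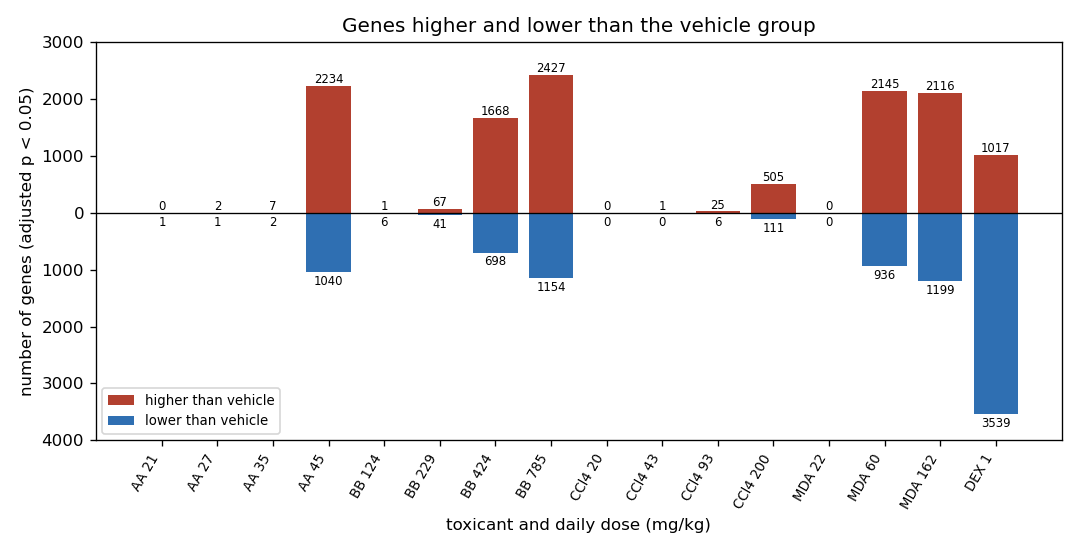
Number of genes higher (red, upward) and lower (blue, downward) than the vehicle group at adjusted p < 0.05 for each toxicant and daily dose in mg/kg (AA allyl alcohol, BB bromobenzene, CCl4 carbon tetrachloride, MDA 4,4'-methylenedianiline, DEX dexamethasone). Allyl alcohol had 9 genes at 35 mg/kg (1629 without replicate 1) and 3274 at 45 mg/kg. With array medians set equal the larger side changed at all 5 top doses, for dexamethasone from 3539 lower and 1017 higher to 1663 and 2178.

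The first comparison asked what allyl alcohol, which the liver oxidises to acrolein, did to hepatic gene expression. At 45 mg/kg Lcn2, which encodes the siderophore-binding acute phase protein lipocalin 2, rose by 7.02 ± 1.23 (130-fold, adjusted p = 5e-04), from a level of 5.44 ± 0.57 (n = 5) to 12.46 ± 0.27 (n = 4). The drug efflux pump gene Abcb1b rose 25-fold (4.64 ± 0.90), the imprinted non-coding RNA H19 20.9-fold (4.39 ± 0.99), the aldo-keto reductase gene Akr1b8 20.4-fold (4.35 ± 0.48), the guanylate cyclase receptor gene Gucy2c 17.7-fold (4.15 ± 0.66) and the macrophage glycoprotein gene Gpnmb 15.1-fold (3.92 ± 0.61). The male-predominant cytochrome P450 gene Cyp2c11 fell by 5.45 ± 0.94 on the log2 scale, from 11.91 ± 0.14 to 6.46 ± 0.54 (adjusted p = 0.00046). Dhrs7l1 (-4.93 ± 0.94), Stac3 (-4.92 ± 0.86), the male urinary protein family gene Obp3 (-4.26 ± 0.81), the carbonic anhydrase gene Car3 (-3.41 ± 0.68) and Sult1c2al1 (-3.23 ± 0.66) fell as well. In all, 3274 of 11234 genes changed at this dose, 2234 higher and 1040 lower, of which 1003 changed at least 2-fold. The share of higher genes was 68.2%, against 31.8% with array medians set equal and 46.5% after quantile normalization. Leaving out replicate 3 of this dose gave 2122 genes.

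Genes of connective tissue and of non-parenchymal cells rose together at 45 mg/kg. Of 24 measured extracellular matrix genes, 17 rose and 7 did not pass (21 rose adjusted over the list alone), with the metalloproteinase inhibitor gene Timp1 at 3.52 ± 0.68 and Postn at 3.46 ± 1.03. Of 13 stellate cell and myofibroblast markers, 8 rose and 5 did not pass (9 adjusted over the list alone), among them the intermediate filament genes Vim (2.53 ± 0.47) and Des (2.21 ± 0.48). In addition, 6 of 13 endothelial markers rose (9 adjusted over the list alone), led by the endothelial cadherin gene Cdh5 (1.05 ± 0.17) and Tie1 (0.87 ± 0.18). Camera's adjusted p was 7.79e-06, 0.000148 and 0.00532 for these 3 lists, with adjusted p = 0.34 for each with an estimated correlation. Of 12 cholangiocyte markers, 11 rose, both over all genes and adjusted over the list alone, with Cd24 at 1.78 ± 0.34 and Bicc1 at 1.66 ± 0.31. Of 18 macrophage markers, 15 rose, led by Gpnmb and the galectin gene Lgals3 (3.07 ± 0.43), and 1, the Kupffer cell lectin gene Clec4f (-0.54 ± 0.20), fell. Of 10 neutrophil markers, 7 rose, led by the gelatinase gene Mmp9 (2.33 ± 0.26) and the integrin gene Itgam (2.15 ± 0.32), with the same counts for both lists adjusted over the list alone. The adjusted p by camera was 2.92e-05, 2.16e-06 and 0.00125 for the cholangiocyte, macrophage and neutrophil markers, with adjusted p = 0.21 for each with an estimated correlation. Col1a1 rose by 2.51 ± 0.92 and the duct keratin gene Krt19 by 0.98 ± 0.34, and Krt7 was at 0.96 ± 0.50 without passing (adjusted p = 0.15).

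Cell division and inflammation genes were also higher. Of 23 proliferation genes, 19 rose (22 adjusted over the list alone), with the mitotic kinase gene Plk1 at 2.45 ± 0.66 and the mitotic kinesin gene Kif20a at 2.36 ± 0.74. The list's camera adjusted p was 1.04e-05, with adjusted p = 0.38 with an estimated correlation. Of 18 acute phase protein genes, 12 rose and 3 fell (14 and 3 adjusted over the list alone), with Lcn2 and the protease inhibitor gene A2m (3.69 ± 0.71) up and the pentraxin gene Apcs (-0.81 ± 0.15) down. With camera the adjusted p was 0.00125, with adjusted p = 0.34 with an estimated correlation. Of 20 inflammatory cytokines and adhesion molecules, 15 rose and 2 fell (16 and 2 adjusted over the list alone), with the chemokine genes Ccl2 (3.56 ± 0.38) and Cxcl16 (2.02 ± 0.29) up and Cxcl11 (-0.68 ± 0.16) down. For this list camera gave an adjusted p of 2.92e-05, and adjusted p = 0.21 with an estimated correlation. Of 22 targets of NRF2, the transcription factor of the electrophile response, 9 rose, with Akr1b8 and the glutathione peroxidase gene Gpx2 (2.87 ± 0.40) leading, and 9 rose and 1 fell adjusted over the list alone. Nqo1 rose by 1.87 ± 0.47 and Hmox1 by 2.70 ± 0.30. Of 17 glutathione transferase genes, 2 rose and 2 fell (2 and 5 adjusted over the list alone): Gstp1 rose by 2.12 ± 0.43, while Gstm7 (-2.09 ± 0.47) and Gstt2 (-0.51 ± 0.15) fell. The NRF2 and transferase lists shifted in opposite directions with a camera adjusted p of 0.0298 each and adjusted p = 0.34 for each with an estimated correlation.

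Metabolic genes of the hepatocyte were lower. Of 28 cytochrome P450 genes of xenobiotic and steroid metabolism, 15 fell and 2 rose (17 and 4 adjusted over the list alone), with Cyp2c11 and Cyp2b2 (-2.64 ± 0.60) down and Cyp1a1 (1.22 ± 0.32) up. Of 11 hepatocyte secreted proteins, 5 fell and 1 rose (6 and 1 adjusted over the list alone), with the corticosteroid-binding globulin gene Serpina6 (-1.74 ± 0.36) and Igfals (-1.50 ± 0.25) down and the complement gene C9 (0.52 ± 0.17) up. Of 24 amino acid and urea cycle enzymes, 12 fell (16 adjusted over the list alone), led by the histidine ammonia-lyase gene Hal (-1.82 ± 0.43) and the glycine methyltransferase gene Gnmt (-1.81 ± 0.41). Camera gave an adjusted p of 8.01e-06, 0.000471 and 1.42e-07 for these 3 lists, with adjusted p = 0.21 for each with an estimated correlation. Of 13 fatty acid synthesis genes, 9 fell, both over all genes and adjusted over the list alone, among them Srebf1 (-1.59 ± 0.28) and the liver pyruvate kinase gene Pklr (-1.38 ± 0.40). Of 16 cholesterol synthesis genes, 6 fell (7 adjusted over the list alone), with the sterol reductase gene Tm7sf2 at -0.82 ± 0.19 and the sterol desaturase gene Sc5d at -0.60 ± 0.12. The camera adjusted p of the fatty acid and cholesterol lists was 9.69e-06 and 3.99e-05, with adjusted p = 0.21 for each with an estimated correlation. Of 8 periportal hepatocyte genes, 5 fell, both over all genes and adjusted over the list alone, with the apolipoprotein gene Apoa4 at -3.13 ± 0.57. Tested by camera, the list had an adjusted p of 0.00114 and an adjusted p = 0.32 with an estimated correlation. Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis (0.60 ± 0.62), and Tat (-0.23 ± 0.30) did not pass, with adjusted p = 0.5 and 0.6. The pericentral genes, bile acid, p53, unfolded protein, heat shock, interferon, fatty acid oxidation, glucocorticoid, circadian, lymphocyte and erythroid lists were not called. The interferon genes, 3 higher and 1 lower, were 1 higher and 5 lower with array medians set equal. In an exact permutation test on both sides of each list's mean per animal, relative to the median of all genes on the array, 16 of 28 lists passed. These were the 17 called lists except the endothelial markers (exact p = 0.127), each at the smallest p that 4 against 5 animals allow, 0.00794.

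At lower doses of allyl alcohol the number of changed genes depended on the fit. With all 96 arrays in 1 fit limma called 0 genes at 21, 890 at 27 and 1698 at 35 mg/kg, and with array weights 2535 at 35 mg/kg, against 1, 3 and 9 in the fit of this exposure, which follow. At 21 mg/kg 1 gene, Cib2, which encodes a calcium- and integrin-binding protein, fell by 1.76 ± 0.22 (adjusted p = 0.00088). It fell by 1.59 ± 0.24 at 27 mg/kg, 1.95 ± 0.24 at 35 mg/kg and 2.00 ± 0.24 at 45 mg/kg. At 27 mg/kg the acute phase gene Orm1 (2.22 ± 0.36) and the mitochondrial phosphoenolpyruvate carboxykinase gene Pck2 (0.91 ± 0.15) also rose, making 3 genes. Camera called 14 lists at 27 mg/kg and 15 at 35 mg/kg, none with an estimated correlation. The exact permutation test passed 0 of 28 list means at either dose, where an adjusted p under 0.05 needs at least 5 lists of low p together, so that a single list cannot pass. At 35 mg/kg 9 genes changed, 7 higher and 2 lower (10 and 20 with array medians set equal), with Orm1 (2.02 ± 0.36), Hebp2 (1.46 ± 0.27) and Ugt2b34l1 (1.18 ± 0.15) up and Cib2 and Meiob (-1.08 ± 0.19) down. These 2 counts rested on single animals. At 35 mg/kg limma called 1629 genes without replicate 1, 32 without replicate 2, 2 without replicate 3 or replicate 4, 4 without vehicle replicate 1 and 5 without vehicle replicate 5. At 27 mg/kg it called 111 without replicate 3, 0 without replicate 2 or replicate 5 and 1 without vehicle replicate 5, where 1836 genes had an unadjusted p under 0.05 with all 4 animals. Along the dose range 3562 genes had a slope, 2445 rising and 1117 falling, and 3074 of them were also called at 45 mg/kg. Between 45 and 35 mg/kg 4 genes differed (1261 at an unadjusted p under 0.05).

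**Figure D2:**
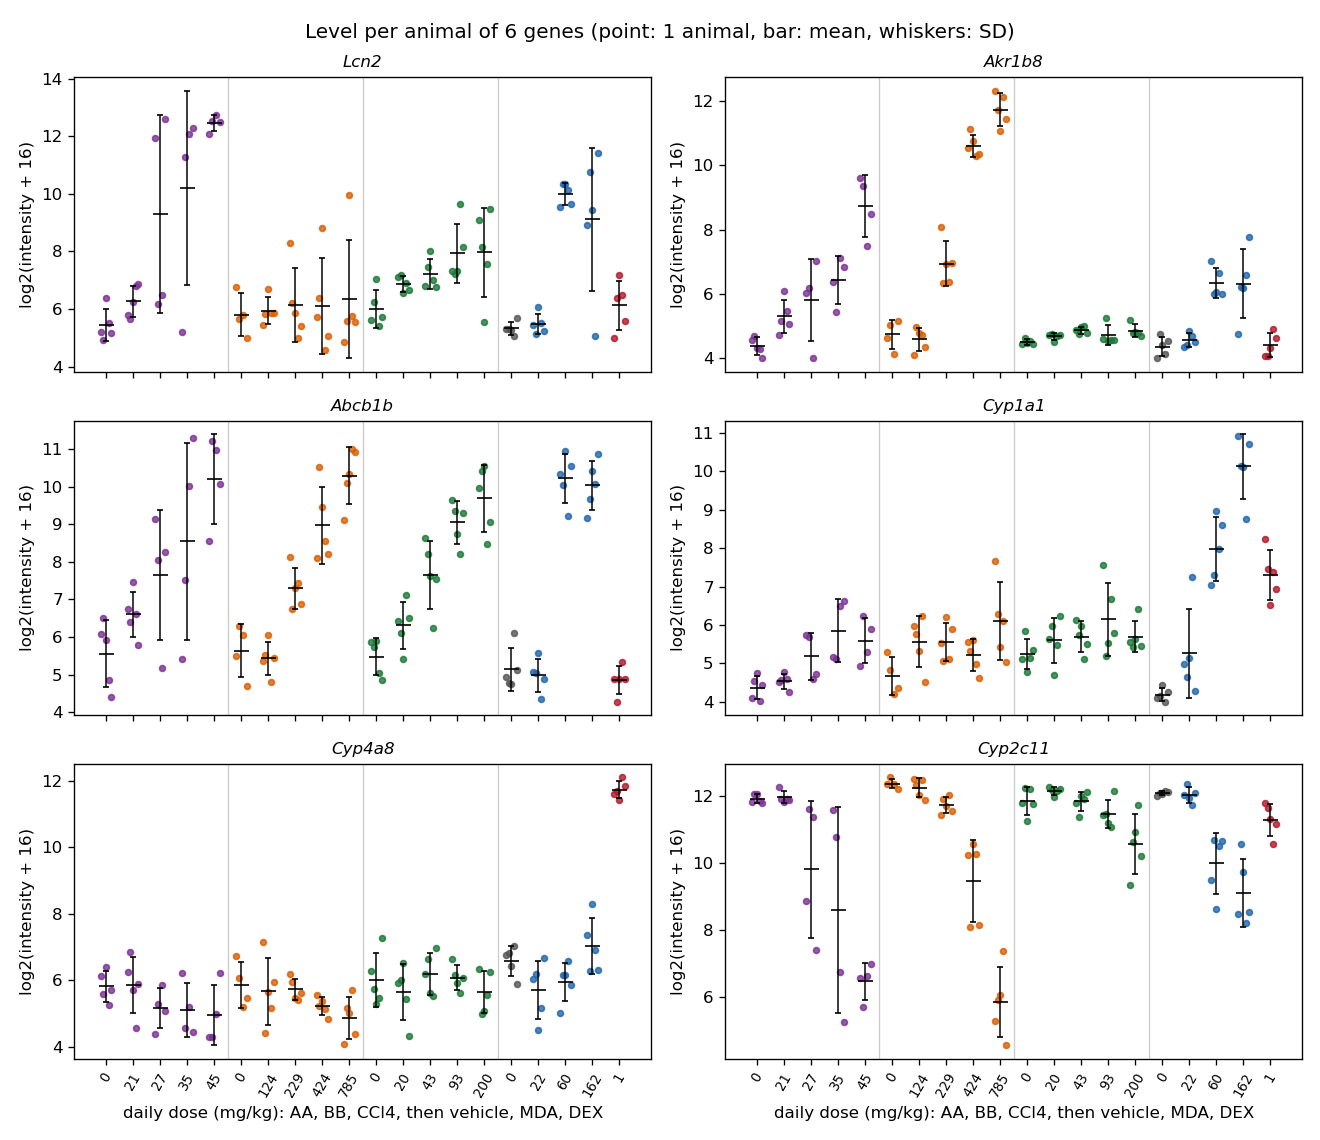
Level, log2(intensity + 16), of 6 genes in each of the 96 animals by daily dose in mg/kg, with the group mean as a bar and the SD as whiskers (AA, BB and CCl4 with their own vehicle at 0, then the shared vehicle, MDA and DEX). Lcn2 averaged 12.46 at 45 mg/kg allyl alcohol against 5.44 in its vehicle animals, and Cyp4a8 averaged 11.73 under dexamethasone against 6.58 in the shared vehicle animals.

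Bromobenzene, which is bioactivated by cytochromes P450 to a reactive epoxide that depletes glutathione, was led by the electrophile response. At 785 mg/kg Akr1b8 rose by 6.99 ± 0.30 (127-fold, adjusted p = 4.2e-14), from 4.75 ± 0.46 (n = 4) to 11.74 ± 0.52 (n = 5). The monocarboxylate transporter gene Slc16a5 rose 55.9-fold (5.80 ± 0.38), the aldo-keto reductase gene Akr1b7 33.9-fold (5.08 ± 0.54), Abcb1b 25.3-fold (4.66 ± 0.43), the cystine transporter gene Slc7a11 20.5-fold (4.36 ± 0.50) and Csmd1 17.8-fold (4.15 ± 0.36). Obp3 fell by 6.77 ± 0.71 on the log2 scale, and Cyp2c11 (-6.53 ± 0.46), Dhrs7l1 (-6.36 ± 0.66), Car3 (-6.08 ± 0.30), Stac3 (-5.54 ± 0.55) and Nrep (-4.79 ± 0.40) also fell. In all, 3581 genes changed, 2427 higher and 1154 lower, 630 of them at least 2-fold, with 67.8% higher against 44.1% with array medians set equal and 54.2% after quantile normalization.

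Of 22 NRF2 targets, 20 rose, the same 20 of 22 adjusted over the list alone, with Akr1b8 and Slc7a11 leading, Nqo1 at 3.38 ± 0.38 and Hmox1 at 3.71 ± 0.49. Camera's adjusted p was 4.87e-17, and this call held with an estimated correlation (adjusted p = 0.0081). So did that of the hepatocyte secreted proteins (camera adjusted p = 1e-08, adjusted p = 0.047 with an estimated correlation). Of these 11 genes 9 fell, 9 also adjusted over the list alone, led by Serpina6 (-2.05 ± 0.28) and Igfals (-1.62 ± 0.28). Lipid synthesis genes fell. Of 16 cholesterol synthesis genes, 13 fell and 1 rose (15 and 1 adjusted over the list alone), with the methylsterol oxidase gene Msmo1 (-2.64 ± 0.34) and the isopentenyl isomerase gene Idi1 (-1.98 ± 0.31) down and Ggps1 (0.39 ± 0.14) up. In camera the adjusted p was 1.09e-10, and adjusted p = 0.25 with an estimated correlation. Of 13 fatty acid synthesis genes, 10 fell and 1 rose, 10 and 1 also adjusted over the list alone, with the desaturase gene Scd (-3.94 ± 0.66) and Thrsp (-2.50 ± 0.42) down and the malic enzyme gene Me1 (1.27 ± 0.21) up. The list's camera adjusted p was 2.08e-05, with adjusted p = 0.32 with an estimated correlation. Of 18 acute phase genes, 11 fell and 2 rose, 11 and 2 also adjusted over the list alone, with A2m (-2.48 ± 0.40) and Apcs (-1.47 ± 0.15) down and the metallothionein gene Mt2A (2.65 ± 0.45) up. Of 18 interferon-stimulated genes, 6 fell, 6 also adjusted over the list alone, among them the immunoproteasome gene Psmb8 (-0.90 ± 0.21) and Ifi27 (-0.77 ± 0.24). Of 24 amino acid and urea cycle enzymes 10 fell (10 fell and 1 rose adjusted over the list alone), among them Gnmt (-1.22 ± 0.22) and the cystathionine beta-synthase gene Cbs (-0.88 ± 0.19). The adjusted p by camera was 0.000266, 0.000376 and 0.00117 for the acute phase, interferon and amino acid lists, with adjusted p = 0.34, 0.44 and 0.44 with an estimated correlation.

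Cytochrome P450 genes went both ways under bromobenzene. Of 28, 13 fell and 7 rose, 13 and 7 also adjusted over the list alone, with Cyp2c11 and Cyp3a9 (-2.12 ± 0.39) down and the phenobarbital-inducible gene Cyp2b1 (3.64 ± 0.49) up. For this list camera gave an adjusted p of 0.0276, and adjusted p = 0.44 with an estimated correlation. Of 12 heat shock genes, 7 rose (9 adjusted over the list alone), with Hspa1b at 2.60 ± 0.84 and Hspb1 at 1.48 ± 0.52. Of 23 proliferation genes 7 rose, 7 also adjusted over the list alone, with the kinesin gene Kif11 at 1.22 ± 0.23 and the replication helicase gene Mcm6 at 1.00 ± 0.31. Of 27 PPAR alpha targets and fatty acid oxidation genes, 13 rose and 3 fell, 13 and 3 also adjusted over the list alone, with the thioesterase genes Acot2 (1.68 ± 0.24) and Acot1 (1.23 ± 0.39) up and Cyp4a8 (-1.0 ± 0.39) down. With camera the adjusted p was 0.00671, 0.0384 and 0.0378 for the heat shock, proliferation and fatty acid oxidation lists, with adjusted p = 0.55, 0.63 and 0.55 with an estimated correlation. Of 24 extracellular matrix genes 2 rose and 1 fell (1 and 4 with array medians set equal), of 18 macrophage markers 2 rose and 5 fell, of 13 stellate cell markers 1 rose and 2 fell and of 12 cholangiocyte markers 3 rose. No member of the neutrophil, lymphocyte and endothelial lists passed limma's test (2 neutrophil markers and 1 endothelial marker fell with array medians set equal), and camera called none of these 7 lists. Col1a1 (0.35 ± 0.39), Krt7 (0.16 ± 0.16), Krt19 (-0.28 ± 0.26), Timp1 (0.28 ± 0.32), Lcn2 (0.53 ± 0.83), Cyp7a1 (-1.16 ± 0.48) and Tat (0.14 ± 0.27) did not pass, with adjusted p from 0.07 for Cyp7a1 to 0.74 for Tat. In the exact permutation test of list means 14 of 28 lists passed, 3 higher and 11 lower, the largest shifts being 1.84 for the NRF2 targets and -1.43 for fatty acid synthesis, both at exact p = 0.00794. The circadian clock genes, 5 higher and 3 lower, were 2 higher and 3 lower with array medians set equal.

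The bromobenzene response grew over the lower doses. At 124 mg/kg 7 genes changed, with the methyltransferase gene Inmt (-2.08 ± 0.35), Gimd1 (-1.82 ± 0.33) and Apoa4 (-1.43 ± 0.24) down and Chd1l (0.75 ± 0.14) up. This count was 1 without replicate 1 or vehicle replicate 4, 11 without vehicle replicate 2 and 15 without replicate 5. At 229 mg/kg 108 genes changed, 67 higher and 41 lower (55 and 58 with array medians set equal). These were led by the aldehyde reductase gene Akr7a3 (2.53 ± 0.36), Nqo1 (2.42 ± 0.38) and Akr1b8 (2.19 ± 0.30) up and Obp3 (-3.86 ± 0.71), Inmt (-2.72 ± 0.35) and Stac3 (-2.58 ± 0.55) down. The count was 60 without vehicle replicate 3 and 69 without vehicle replicate 5. At 424 mg/kg 2366 genes changed, 1668 higher and 698 lower (846 and 1314 with array medians set equal). At the head were Akr1b8 (5.86 ± 0.30), Gstp1 (3.72 ± 0.33) and Csmd1 (3.45 ± 0.36) up and Obp3 (-6.09 ± 0.71), Dhrs7l1 (-5.36 ± 0.66) and Stac3 (-4.99 ± 0.55) down. A fit on the 424 mg/kg and vehicle animals alone called 1385 genes. Along the dose range 4392 genes had a slope, 2953 rising and 1439 falling, 3394 of them also called at 785 mg/kg, and 63 genes differed between 785 and 424 mg/kg, 34 higher and 29 lower at the higher dose.

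Carbon tetrachloride, which is bioactivated in the centrilobular hepatocyte, changed 616 genes at its top dose, and 3 of its 6 largest rises were of cell division genes. At 200 mg/kg Abcb1b rose by 4.21 ± 0.41 (18.5-fold, adjusted p = 3.8e-07), from 5.48 ± 0.50 (n = 5) to 9.69 ± 0.90 (n = 5). Gpnmb rose 5.59-fold (2.48 ± 0.22), the cyclin gene Ccna2 4.92-fold (2.30 ± 0.39), the lipoprotein-associated phospholipase gene Pla2g7 4.51-fold (2.17 ± 0.14), the ribonucleotide reductase gene Rrm2 4.38-fold (2.13 ± 0.40) and the mitotic kinase gene Aurkb 4.23-fold (2.08 ± 0.35). Popdc2 (-1.54 ± 0.33), Sez6 (-1.54 ± 0.35), A2m (-1.48 ± 0.32), the neprilysin gene Mme (-1.21 ± 0.24), the caveolin gene Cav2 (-1.11 ± 0.27) and the smooth muscle actin gene Actg2 (-1.03 ± 0.29) fell. Of the 616 genes, 505 were higher and 111 lower, 143 changed at least 2-fold, and 355 genes changed without replicate 3. The share of higher genes was 82%, against 41.4% with array medians set equal and 65.3% after quantile normalization.

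Of 23 proliferation genes, 22 rose (23 adjusted over the list alone), led by Ccna2 and Rrm2. Tested by camera, the list had an adjusted p of 1.04e-23 and an adjusted p = 0.16 with an estimated correlation. Of 18 macrophage markers, 4 rose (6 adjusted over the list alone), with Gpnmb and Lgals3 (1.47 ± 0.23) leading. Of 20 inflammatory genes 3 rose, 3 also adjusted over the list alone, with Ccl2 at 1.53 ± 0.27 and Cxcl16 at 1.17 ± 0.19. Of 16 p53 targets, 2 rose and 1 fell (5 and 1 adjusted over the list alone): Ccng1 (0.95 ± 0.14) and Eda2r (0.85 ± 0.14) rose and Xpc (-0.51 ± 0.13) fell. Camera gave an adjusted p of 4.63e-05, 0.0227 and 0.0379 for these 3 lists, with adjusted p = 0.42 for each with an estimated correlation. Of 22 NRF2 targets, 2 rose, 2 also adjusted over the list alone, Akr7a3 (0.96 ± 0.24) and Gpx2 (0.84 ± 0.19). Of 27 fatty acid oxidation genes 3 rose (6 adjusted over the list alone), with Acot2 at 1.22 ± 0.15 and Cyp4a1 at 1.08 ± 0.16. Both lists had a camera adjusted p of 0.0379 and an adjusted p = 0.42 with an estimated correlation. Of 28 cytochrome P450 genes, 5 fell (6 adjusted over the list alone), led by Cyp2c11 (-1.29 ± 0.28) and Cyp3a18 (-1.18 ± 0.29). Of 24 amino acid and urea cycle enzymes 1, the proline dehydrogenase gene Prodh (-0.60 ± 0.12), fell, 1 also adjusted over the list alone. Both had a camera adjusted p of 0.000202, with adjusted p = 0.16 and 0.35 with an estimated correlation. The endothelial and periportal lists were also called lower and the heat shock list higher, at camera adjusted p of 0.0379, 0.0379 and 0.0406 and an adjusted p = 0.42 for each with an estimated correlation. No single member of the 3 passed limma's test. This camera count was 6 without replicate 2 and 5 without vehicle replicate 4. Proliferation had a shift of 1.35 and the smallest exact permutation p these animals allow, 0.00794, which was 0.11 after adjustment; a single list cannot pass after adjustment, since at least 5 of the 28 must have low p together, and none did. Passing genes changed side with array medians set equal for bile acid genes (2 higher and 0 lower to 2 and 3) and acute phase genes (3 and 1 to 3 and 4), neither called by camera.

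Of the genes chosen as markers of injury, Timp1 (1.09 ± 0.12) and Lcn2 (1.96 ± 0.52) rose at 200 mg/kg carbon tetrachloride. Col1a1 (0.07 ± 0.24), Krt7 (-0.14 ± 0.13), Krt19 (0.25 ± 0.20), Nqo1 (0.50 ± 0.30), Hmox1 (0.23 ± 0.16), Cyp7a1 (0.84 ± 0.48) and Tat (0.38 ± 0.22) did not pass, with adjusted p from 0.36 for Cyp7a1 to 0.92 for Col1a1. At 20 mg/kg limma called 0 genes (590 at an unadjusted p under 0.05, about as by chance). At 43 mg/kg it called 1 gene, Pla2g7, up by 0.91 ± 0.14 (adjusted p = 0.0074), and 3 genes without replicate 4. At 93 mg/kg 31 genes changed, 25 higher and 6 lower (14 and 9 with array medians set equal). The largest were Abcb1b (3.57 ± 0.41), Gpnmb (1.78 ± 0.22) and Ccna2 (1.77 ± 0.39) up and the secreted phospholipase gene Pla2g2a (-2.48 ± 0.54), Scel (-0.79 ± 0.13) and Adgrf5 (-0.62 ± 0.11) down. That count was 6 when all 96 arrays were fitted together. Without single animals it was 8 (replicate 1 or replicate 5), 12 (replicate 2), 15 (replicate 3), 14 (replicate 4), 11, 13 and 18 (vehicle replicate 1, replicate 2 and replicate 5). Along the dose range 1027 genes had a slope, 802 rising and 225 falling, 574 of them also called at 200 mg/kg, and between 200 and 93 mg/kg limma called 0 genes (734 at an unadjusted p under 0.05).

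4,4'-Methylenedianiline, an aromatic diamine known to injure bile duct epithelium, raised inflammatory genes. At 162 mg/kg Cyp1a1, a target of the aryl hydrocarbon receptor, rose by 5.94 ± 0.45 (61.4-fold, adjusted p = 4.9e-10), from 4.19 ± 0.17 (n = 5) to 10.13 ± 0.84 (n = 5). The ubiquitin-like modifier gene Ubd rose 32.1-fold (5.00 ± 0.67), the retinoic acid hydroxylase gene Cyp26a1 30.7-fold (4.94 ± 0.37), Abcb1b 29.7-fold (4.89 ± 0.31), Cyp2b1 21.1-fold (4.40 ± 0.65) and the oncostatin M receptor gene Osmr 13.4-fold (3.74 ± 0.33). Car3 (-6.59 ± 0.72), Dhrs7l1 (-5.98 ± 0.58), Stac3 (-5.64 ± 0.37), Obp3 (-4.24 ± 0.67), the sterol transporter gene Abcg5 (-4.01 ± 0.28) and Sult1c2al1 (-3.32 ± 0.24) fell. In all, 3315 genes changed, 2116 higher and 1199 lower, 606 of them at least 2-fold, with 63.8% higher against 39.2% with array medians set equal and 51.8% after quantile normalization.

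Duct, matrix and immune cell genes rose at 162 mg/kg. Of 12 cholangiocyte markers, 10 rose (11 adjusted over the list alone), with Krt8 at 1.81 ± 0.17 and Bicc1 at 1.79 ± 0.18. In camera the adjusted p was 2.15e-07, and adjusted p = 0.19 with an estimated correlation. Krt7 (1.15 ± 0.21) and Krt19 (0.84 ± 0.22) were among those that rose. Of 24 extracellular matrix genes, 11 rose and 1 fell (11 and 3 adjusted over the list alone), with Postn (2.41 ± 0.29) and Col1a1 (1.92 ± 0.27) up and the biglycan gene Bgn (-0.66 ± 0.16) down. The list's camera adjusted p was 0.00139, with adjusted p = 0.35 with an estimated correlation. Of 18 macrophage markers, 11 rose and 1 fell (12 and 2 adjusted over the list alone), with Gpnmb (3.31 ± 0.24) and Lgals3 (2.23 ± 0.21) up and the lipopolysaccharide co-receptor gene Cd14 (-0.56 ± 0.17) down. Of 12 lymphocyte markers, 8 rose and 2 fell, 8 and 2 also adjusted over the list alone, with the leukocyte phosphatase gene Ptprc (1.29 ± 0.16) and Il7r (1.19 ± 0.26) up and the T cell receptor gene Cd3d (-0.57 ± 0.13) down. Camera's adjusted p was 7.62e-06 and 0.0101 for these 2 lists, with adjusted p = 0.24 for each with an estimated correlation. Of 20 inflammatory genes, 13 rose (15 adjusted over the list alone), led by Cxcl16 (3.13 ± 0.26) and Ccl2 (3.01 ± 0.27). For this list camera gave an adjusted p of 1.03e-08, and adjusted p = 0.073 with an estimated correlation. Of 18 interferon-stimulated genes, 7 rose, 7 also adjusted over the list alone, with Gbp5 at 3.11 ± 0.26 and Oasl at 1.78 ± 0.30. Of 23 proliferation genes 12 rose (15 adjusted over the list alone), with Mcm3 at 1.16 ± 0.24 and Mcm6 at 1.12 ± 0.19. The adjusted p by camera was 0.00139 and 0.000104, with adjusted p = 0.35 for each with an estimated correlation. Of 18 acute phase genes, 10 rose and 1 fell, 10 and 1 also adjusted over the list alone, with Lcn2 (3.79 ± 0.67) and Osmr up and Apcs (-0.70 ± 0.12) down. Tested by camera, the list had an adjusted p of 0.00363 and an adjusted p = 0.24 with an estimated correlation. Timp1 rose by 1.75 ± 0.28.

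Stress genes rose and metabolic genes fell at the same dose. Of 22 NRF2 targets, 9 rose and 1 fell (12 and 1 adjusted over the list alone), with Gpx2 (3.03 ± 0.35) and Akr1b8 (1.95 ± 0.33) up and Aldh3a1 (-0.44 ± 0.13) down. Nqo1 rose by 1.48 ± 0.18 and Hmox1 by 1.12 ± 0.26. Of 16 p53 targets 7 rose and 1 fell (9 and 1 adjusted over the list alone), with the stress cytokine gene Gdf15 (2.11 ± 0.25) and Plk3 (1.09 ± 0.29) up and Sesn2 (-0.58 ± 0.18) down. With camera the adjusted p was 0.000714 and 0.0449, with adjusted p = 0.24 for each with an estimated correlation. Of 12 heat shock genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with the small heat shock gene Cryab (1.64 ± 0.22) and Hspa1b (1.29 ± 0.28) up and Dnaja1 (-0.32 ± 0.09) down. In camera the adjusted p was 0.0418, and adjusted p = 0.35 with an estimated correlation. Of 27 fatty acid oxidation genes, 14 fell (15 adjusted over the list alone), with the lipase inhibitor gene Angptl4 at -1.52 ± 0.36 and Cyp4a1 at -0.96 ± 0.30. Of 24 amino acid and urea cycle enzymes 11 fell (12 adjusted over the list alone), with Hal at -1.68 ± 0.29 and Agxt at -1.04 ± 0.19. Of 13 fatty acid synthesis genes 4 fell (5 adjusted over the list alone), with Pklr at -1.60 ± 0.27 and Dgat2 at -1.13 ± 0.16. Camera gave an adjusted p of 2.66e-07, 5.92e-06 and 0.00712 for these 3 lists, with adjusted p = 0.24 for each with an estimated correlation. Of 8 periportal genes 3 fell, 3 also adjusted over the list alone, with Apoa4 (-2.71 ± 0.23) and Hal leading. Of 14 pericentral genes 5 fell and 2 rose, 5 and 2 also adjusted over the list alone, with the ornithine aminotransferase gene Oat (-2.46 ± 0.37) and Gulo (-1.82 ± 0.20) down and Aldh1a1 (1.77 ± 0.31) up. Camera's adjusted p was 0.00411 and 0.00778, with adjusted p = 0.24 for each with an estimated correlation. Of 11 hepatocyte secreted proteins 6 fell and 2 rose, 6 and 2 also adjusted over the list alone, with Serpina6 (-2.45 ± 0.23) and Apoa2 (-0.81 ± 0.16) down and C9 (0.61 ± 0.14) up. The list's camera adjusted p was 0.00363, with adjusted p = 0.073 with an estimated correlation. Of 16 cholesterol synthesis genes 3 fell and 1 rose, 3 and 1 also adjusted over the list alone, with Tm7sf2 (-1.0 ± 0.25) and Ebp (-0.51 ± 0.14) down and Insig1 (0.79 ± 0.28) up. For this list camera gave an adjusted p of 0.0449, and adjusted p = 0.56 with an estimated correlation. Cyp7a1 (-0.09 ± 0.53) and Tat (0.09 ± 0.21) did not pass (adjusted p = 0.93 and 0.8). In the exact permutation test 20 of 28 list means passed, 12 higher and 8 lower. The P450 genes (8 higher, 10 lower) and endothelial markers (1 and 0, or 1 and 2 with array medians set equal) were not called.

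At 60 mg/kg 4,4'-methylenedianiline changed 3081 genes, 2145 higher and 936 lower (1288 and 2304 with array medians set equal). The largest changes were Abcb1b (5.08 ± 0.31), Lcn2 (4.67 ± 0.67) and Cyp1a1 (3.79 ± 0.45) up and Stac3 (-5.19 ± 0.37), Dhrs7l1 (-4.92 ± 0.58) and Car3 (-4.48 ± 0.72) down. At this dose 18 of 28 list means passed the exact permutation test. At 22 mg/kg limma called 0 genes (457 at an unadjusted p under 0.05). Between 162 and 60 mg/kg 15 genes differed, 5 higher and 10 lower at the higher dose. The retinoic acid hydroxylase genes Cyp26a1 (3.33 ± 0.37) and Cyp26b1 (2.53 ± 0.37) and Cyp1a1 (2.15 ± 0.45) were higher. Cyp26b1 was chosen after its values were seen. Along the dose range 3386 genes had a slope, 2137 rising and 1249 falling, 3010 of them also called at 162 mg/kg.

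**Figure D3:**
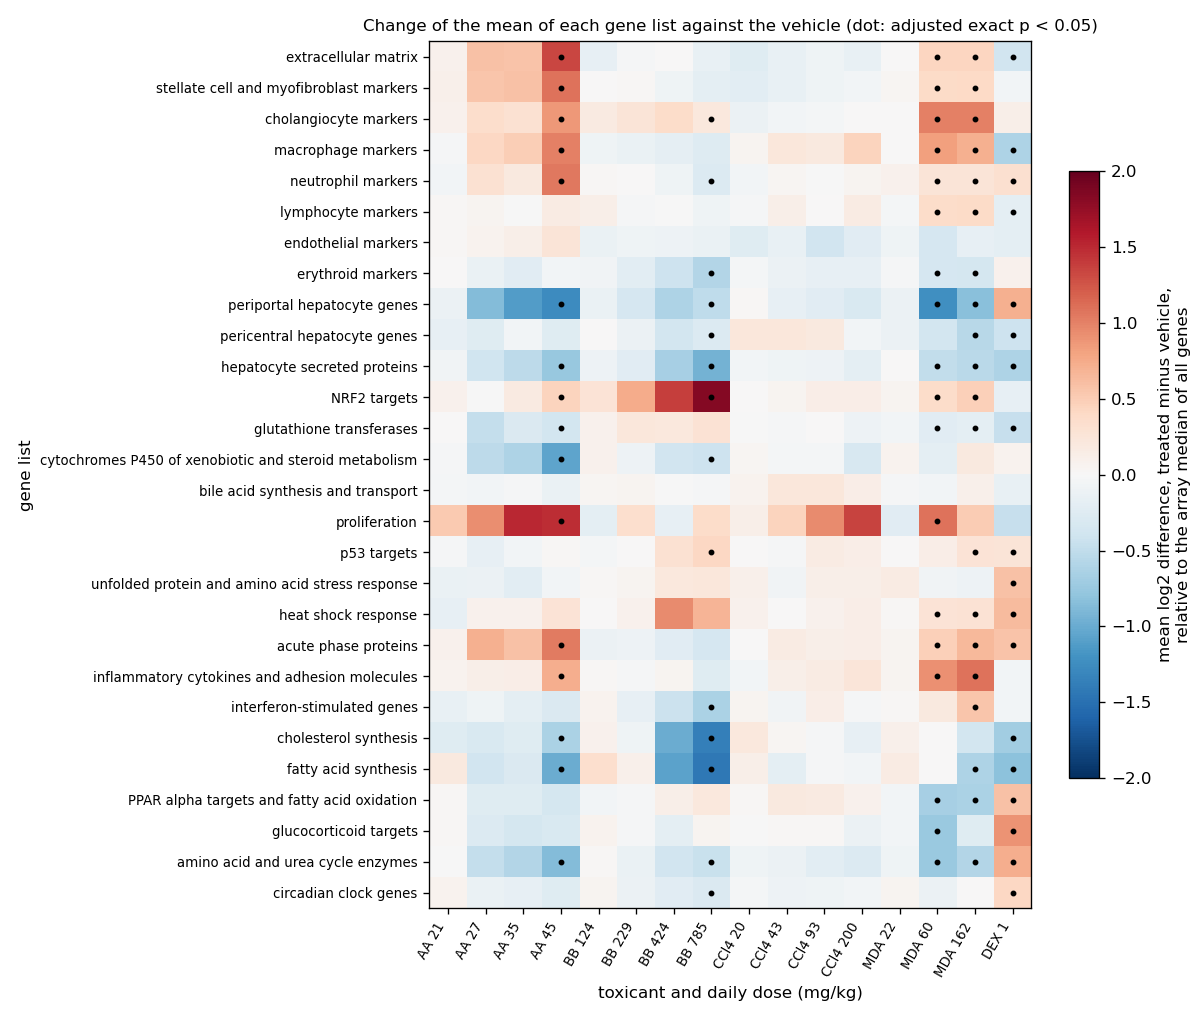
Colour gives the mean log2 difference between treated and vehicle animals of each of 28 gene lists, relative to the median of all genes on the array, for each toxicant and daily dose in mg/kg; a dot marks an adjusted exact permutation p under 0.05. The differences ran from -1.43 for fatty acid synthesis to 1.84 for the NRF2 targets, both at 785 mg/kg bromobenzene, and dots stand at the top dose of allyl alcohol and bromobenzene, at 60 and 162 mg/kg 4,4'-methylenedianiline and under dexamethasone.

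Dexamethasone, a synthetic glucocorticoid, was given at 1 mg/kg and compared with the vehicle animals of the 4,4'-methylenedianiline exposure. The median of all genes moved by -0.19 on the log2 scale, and the changes of single genes under dexamethasone are given relative to it. Levels, adjusted p and the calls of genes that rose, fell or did not pass are those before it was taken off. Cyp4a8 stood 5.34 ± 0.36 higher (5.15 before the median was taken off, adjusted p = 4.3e-11), from 6.58 ± 0.45 (n = 5) to 11.73 ± 0.26 (n = 5). The protease gene Prss32 (4.51 ± 0.36), Faxdc2 (4.49 ± 0.19), the formin gene Diaph3 (4.33 ± 0.29), Plppr1 (3.76 ± 0.31) and Fbxl17l1 (3.5 ± 0.19) rose. Car3 (-6.18 ± 0.72), Stac3 (-5.23 ± 0.37), the desaturase gene Fads2 (-5.20 ± 0.23), Serpina6 (-5.14 ± 0.23), Nrep (-4.71 ± 0.31) and the steroid dehydrogenase gene Hsd17b2 (-4.28 ± 0.34) fell. In all, 4556 genes changed, 1017 higher and 3539 lower, 711 of them at least 2-fold. The share of higher genes was 22.3%, against 56.7% with array medians set equal (2178 higher and 1663 lower) and 50% after quantile normalization. The median intensity of the dexamethasone arrays lay between 17.34 and 19.43, and that of the vehicle arrays between 21.55 and 23.28.

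Of 18 glucocorticoid targets, 12 rose and 2 fell, 12 and 2 also with array medians set equal and adjusted over the list alone, with the FK506-binding protein gene Fkbp5 (2.77 ± 0.22) and Zbtb16 (2.14 ± 0.43) up and Abcb1a (-1.22 ± 0.26) down. Of 24 amino acid and urea cycle enzymes, 16 rose and 2 fell (18 and 1 with array medians set equal, 16 and 2 adjusted over the list alone), with the transaminase genes Gpt (2.33 ± 0.34) and Got1 (1.71 ± 0.28) up and Kmo (-1.73 ± 0.14) down. Of 8 periportal genes 5 rose in each, 5 also adjusted over the list alone, with the urea cycle genes Ass1 (1.42 ± 0.17) and Arg1 (1.22 ± 0.18) leading. The adjusted p by camera was 9.08e-06, 4.67e-08 and 0.000746 for these 3 lists, with adjusted p = 0.22 for each with an estimated correlation. Of 25 unfolded protein and amino acid stress genes, 10 rose and 3 fell (15 and 2 with array medians set equal, 12 and 3 adjusted over the list alone), with Fgf21 (1.69 ± 0.54) and Creld2 (1.66 ± 0.28) up and Vldlr (-0.74 ± 0.25) down. Of 12 heat shock genes 6 rose and 1 fell, 6 and 1 also adjusted over the list alone, with Hspa1b (1.44 ± 0.28) and Hsph1 (0.96 ± 0.18) up and Hspa4 (-0.11 ± 0.10) lower. Of 18 acute phase genes 8 rose and 1 fell, 8 and 1 also adjusted over the list alone, with Orm1 (1.80 ± 0.20) and Mt2A (1.35 ± 0.44) up and Hpx (-0.08 ± 0.09) lower. With array medians set equal 9 rose in each list and neither Hspa4 nor Hpx fell. With camera the adjusted p was 5.83e-05, 0.000373 and 0.000584 for these 3 lists, with adjusted p = 0.22 for each with an estimated correlation. Of 27 fatty acid oxidation genes, 6 rose and 4 fell (12 and 3 with array medians set equal, 6 and 4 adjusted over the list alone), with Cyp4a8 and the peroxisome gene Pex11a (1.92 ± 0.21) up and Ehhadh (-1.30 ± 0.14) down. Tested by camera, the list had an adjusted p of 0.00102 and an adjusted p = 0.49 with an estimated correlation.

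Matrix, macrophage, cell division, transferase and cholesterol genes fell under dexamethasone. Of 24 extracellular matrix genes, 17 fell and 2 rose (13 and 4 with array medians set equal, 17 and 3 adjusted over the list alone), with Col1a1 (-1.71 ± 0.27) and Col3a1 (-1.27 ± 0.18) down and the decorin gene Dcn (1.52 ± 0.37) up. Of 18 macrophage markers 14 fell (12 fell and 1 rose with array medians set equal, 14 adjusted over the list alone), with Adgre1 (-1.54 ± 0.18) and the complement gene C1qa (-1.41 ± 0.17) leading. Camera gave an adjusted p of 0.00756 and 0.000746, with adjusted p = 0.49 and 0.3 with an estimated correlation. Of 23 proliferation genes, 18 fell and 1 rose (10 and 1 with array medians set equal, 19 and 1 adjusted over the list alone), with Ccna2 (-1.28 ± 0.28) and Rrm2 (-1.23 ± 0.44) down. The gene that rose was Mcm3 (1.87 ± 0.24), whose 2 probe sets disagreed, at 1.69 and -0.40 before the median was taken off. Of 17 glutathione transferase genes 10 fell (7 fell and 1 rose with array medians set equal, 10 adjusted over the list alone), led by Gstt3 (-2.01 ± 0.27) and Gstm3 (-1.10 ± 0.33). Of 16 cholesterol synthesis genes 11 fell and 1 rose (10 and 1 with array medians set equal, 12 and 1 adjusted over the list alone), with Msmo1 (-1.93 ± 0.33) and Idi1 (-1.81 ± 0.34) down and Hsd17b7 (1.07 ± 0.29) up. Camera's adjusted p was 0.0116, 0.00746 and 0.00169 for the proliferation, transferase and cholesterol lists, with adjusted p = 0.62, 0.22 and 0.49 with an estimated correlation. Nqo1 (1.29 ± 0.18) and Tat (0.74 ± 0.21) rose; Krt7 (0.34 ± 0.21), Krt19 (0.25 ± 0.22), Timp1 (0.82 ± 0.28), Hmox1 (-0.12 ± 0.26), Lcn2 (0.98 ± 0.67) and Cyp7a1 (0.63 ± 0.53) did not pass, and of these Timp1 passed with array medians set equal. In the exact permutation test 18 of 28 list means passed, 10 higher and 8 lower. The majority of passing genes changed side with array medians set equal for the erythroid (0 higher and 1 lower to 1 and 0), P450 (4 and 7 to 5 and 4), p53 (3 and 4 to 6 and 3), inflammatory (3 and 8 to 5 and 3) and circadian lists (1 and 3 to 3 and 1), none of which camera called.

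The toxicants were then set side by side at their top doses, which are not matched in exposure. Abcb1b rose in all 4 injury models, by 4.64, 4.66, 4.21 and 4.89 at the top dose of allyl alcohol, bromobenzene, carbon tetrachloride and 4,4'-methylenedianiline, and was at -0.29 under dexamethasone before the all-gene median of -0.19 was taken off. Of the genes higher in all 4, 126 against 4.1 expected for independent lists, Abcb1b, Gpnmb, Gucy2c, Osmr and Gpx2 had the largest mean change, and 48 genes were lower in all 4 against 0.11 expected. The responses of allyl alcohol and 4,4'-methylenedianiline were the most alike, with r = 0.695 across genes, and allyl alcohol and carbon tetrachloride came next (r = 0.555). The other pairs had r = 0.442 (allyl alcohol and bromobenzene), 0.379 (bromobenzene and carbon tetrachloride), 0.48 (bromobenzene and 4,4'-methylenedianiline), 0.461 (carbon tetrachloride and 4,4'-methylenedianiline), 0.21 (bromobenzene and dexamethasone), 0.101 (4,4'-methylenedianiline and dexamethasone), 0.035 (carbon tetrachloride and dexamethasone) and 0.029 (allyl alcohol and dexamethasone). These correlations run across genes, which are not independent replicates, and for dexamethasone and allyl alcohol Spearman's rho was -0.036. The 4,4'-methylenedianiline and dexamethasone comparisons share vehicle animals. In them, 100 simulations of unchanged groups against shared controls gave a mean r of 0.5 and a covariance of 0.0147 against an observed covariance of 0.0281. With the vehicle animals split between the comparisons r averaged 0.044 (range -0.004 to 0.087). There 224 genes were higher in both (192 expected for independent lists), 572 lower in both (378 expected) and 1061 opposite (775 expected). Part of the excess in the same direction may come from the shared vehicle, which by itself would make the comparisons more alike and not add opposite genes.

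The test of the difference between responses, in a fit of all 96 arrays, called 563 genes between allyl alcohol and 4,4'-methylenedianiline, 337 with the first response above the second and 226 below. The largest differences were A2m (difference 4.01 ± 0.71) and H19 (3.40 ± 0.84) above and Cyp2b1 (-6.12 ± 0.78) and Cyp1a1 (-4.72 ± 0.59) below. That count was 338 without allyl alcohol replicate 3 and 856 without replicate 5. Allyl alcohol and bromobenzene differed in 2299 genes (1232 and 1067), led by Lcn2 (6.49 ± 1.31) and A2m (6.17 ± 0.73) above and Slc16a5 (-5.72 ± 0.41) and Cyp2b1 (-5.36 ± 0.80) below. Allyl alcohol and carbon tetrachloride differed in 1327 (872 and 455), led by A2m (5.17 ± 0.71) and Lcn2 (5.06 ± 1.27) above and Cyp2c11 (-4.17 ± 0.83) and Cyp2b2 (-3.19 ± 0.54) below. The count was 703 without allyl alcohol replicate 3. Bromobenzene and carbon tetrachloride differed in 1488 (859 and 629), led by Akr1b8 (6.64 ± 0.49) and Slc16a5 (5.92 ± 0.40) above and Car3 (-5.55 ± 0.80) and Cyp2c11 (-5.24 ± 0.83) below. Bromobenzene and 4,4'-methylenedianiline differed in 1806 (937 and 869), led by Akr1b8 (5.04 ± 0.49) and Slc16a5 (4.89 ± 0.40) above and Ubd (-6.24 ± 0.94) and Cyp1a1 (-4.50 ± 0.59) below. Carbon tetrachloride and 4,4'-methylenedianiline differed in 887 (399 and 488), led by Car3 (6.05 ± 0.78) and Abcg5 (4.00 ± 0.66) above and Cyp1a1 (-5.49 ± 0.57) and Cyp26a1 (-5.20 ± 0.40) below.

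Each injury model differed from dexamethasone in many genes, with the median shift of dexamethasone entering these differences. Allyl alcohol and dexamethasone differed in 4581 genes (3616 and 965), with Lcn2 (6.23 ± 1.27) and Abcb1b (4.93 ± 0.82) above and Cyp4a8 (-6.02 ± 0.60) and Obp3 (-5.13 ± 1.19) below. Bromobenzene differed from it in 4236 (3436 and 800), with Akr1b8 (6.95 ± 0.49) and Csmd1 (5.83 ± 0.48) above and Obp3 (-7.64 ± 1.19) and Cyp4a8 (-6.15 ± 0.60) below. Carbon tetrachloride differed from it in 3323 (2751 and 572), with Car3 (5.83 ± 0.78) and Fads2 (5.48 ± 0.31) above and Cyp4a8 (-5.52 ± 0.58) and Faxdc2 (-4.38 ± 0.31) below. 4,4'-Methylenedianiline and dexamethasone, a direct comparison of treated animals, differed in 5468 (4173 and 1295), with Ubd (5.48 ± 0.64) and the MHC class II gene RT1-Da (5.44 ± 0.25) above and Obp3 (-5.11 ± 0.82) and Dhrs7l1 (-4.81 ± 0.81) below. The 4 vehicle groups themselves differed in 3899 genes in an F test of 19 arrays with 3 degrees of freedom, and in 2386 with array medians set equal and 2171 after quantile normalization. Rbp2 was at 4.52 ± 0.04 in the vehicle animals of allyl alcohol and 8.17 ± 0.40, 7.72 ± 0.43 and 8.25 ± 0.16 in those of bromobenzene, carbon tetrachloride and 4,4'-methylenedianiline. Sapcd2 was at 4.47 ± 0.31 against 7.94 ± 0.11, 7.55 ± 0.38 and 7.93 ± 0.27. Ccna1 was at 5.25 ± 0.18 in the vehicle animals of 4,4'-methylenedianiline and from 7.89 to 8.17 in the others, and Ptprz1 at 6.61 ± 0.35 in those of carbon tetrachloride and from 4.09 to 4.54 in the others. No treated group was therefore set against the vehicle of another exposure.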

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

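The medians-equal test of the dexamethasone pattern, the vehicle animal test at 35 mg/kg allyl alcohol, the hepatocyte share test and all counts of random regroupings were chosen only after the result was seen. Animals far from the rest of their group were looked for among 592 pairs of a named gene and a group by Dixon's criterion, which chance meets in about 1 in 20 groups, and 36 were found. Values are log2(intensity + 16), each followed by the range of the other animals.

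In the allyl alcohol exposure, animals of the 45 mg/kg group stood apart for Timp1 (replicate 3, 11.61 against 9.3 to 9.68), Cyp2b2 (replicate 1, 8.83 against 6.54 to 6.82) and Nqo1 (replicate 1, 10.41 against 9.91 to 9.96). Vehicle animals did so for Nqo1 (replicate 2, 6.18 against 8.31 to 9.08), Cib2 (replicate 5, 8.1 against 6.69 to 6.93), Gpx2 (replicate 3, 5.86 against 4.26 to 4.55), Postn (replicate 3, 4.7 against 4.09 to 4.26), A1bg (replicate 4, 5.94 against 4.63 to 4.98) and Ccl2 (replicate 5, 4.54 against 4.87 to 5). With bromobenzene, Lcn2 was at 9.95 in replicate 3 at 785 mg/kg against 4.85 to 5.74, Stac3 at 4.05 in replicate 5 against 4.43 to 4.53 and Timp1 at 7.98 in replicate 4 against 7.35 to 7.51. Stac3 was at 6.87 in replicate 1 at 424 mg/kg (4.06 to 4.78) and Akr7a3 at 12.36 in replicate 4 at 229 mg/kg (12.01 to 12.08). Bromobenzene vehicle animals stood apart for Cyp2b1 (replicate 5, 4.99 against 7.61 to 7.66), A2m (replicate 4, 8.59 against 9.52 to 9.62), Hspb1 (replicate 3, 6.31 against 5.76 to 5.84) and Igfals (replicate 5, 10.56 against 10.42 to 10.43). Sapcd2 was at 8.21 in carbon tetrachloride vehicle replicate 5 (7.29 to 7.47).

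At 162 mg/kg 4,4'-methylenedianiline, replicate 2 stood apart for Car3 (9.36 against 4.88 to 5.86) and Dhrs7l1 (7.73 against 4.19 to 5.19), and replicate 4 for Hmox1 (9.44 against 8.29 to 8.62). Under dexamethasone, Fgf21 was at 6.92 in replicate 2 (7.75 to 8.08), and replicate 3 stood apart for Hsd17b7 (8.33 against 8.92 to 9.13) and Orm1 (12.1 against 11.72 to 11.8). In the vehicle group these exposures share, replicate 5 stood apart for Fgf21 (8.75 against 4.91 to 5.99), Hsd17b2 (10.53 against 8.56 to 9.1), Creld2 (7.34 against 8.01 to 8.17), Agxt (8.43 against 9.08 to 9.18) and Ebp (10.1 against 9.55 to 9.67). Replicate 4 did so for Abcb1b (6.11 against 4.74 to 5.13), Aldh3a1 (6.36 against 5.69 to 5.87) and Fbxl17l1 (4.56 against 4.79 to 4.87), replicate 1 for Hmox1 (6.98 against 7.53 to 7.73) and Tat (11.75 against 10.78 to 11.06), and replicate 2 for Ccna1 (4.94 against 5.26 to 5.38).

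Probe sets without a gene name, outside the comparisons of genes, also changed. Of 13368 at or above the floor, limma called 1516 at the top dose of allyl alcohol, 2001 at that of bromobenzene, 171 at that of carbon tetrachloride, 1541 at that of 4,4'-methylenedianiline and 2633 under dexamethasone.

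Dexamethasone lowered more genes than it raised, and a technical factor common to all genes of its arrays would shift bright and unnamed probe sets alike. Of 3 equal classes of genes by vehicle level, the brightest had a median change of -0.25 and the others -0.24 and -0.11. Unnamed probe sets were at -0.16 and all genes at -0.19, as such a factor allows. With array medians set equal 56.7% of called genes were higher, but centring balances the calls, so this decides nothing. Array minima were 1e-05 to 1.1e-05 under dexamethasone and 7e-06 in vehicle arrays. Array processing and a general fall of liver RNA were not tested and stay open.

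At 35 mg/kg allyl alcohol few genes were called with all 4 animals and many without replicate 1. A poor array was argued against, since its highest correlation with another array of the exposure, 0.976, lay above the lowest such value of the other 21 arrays, 0.964. A vehicle animal under this label was argued against too, since in 3 of the 3 genes called at 27 mg/kg (Cib2, Orm1 and Pck2) replicate 1 lay beyond all vehicle animals on the side of the treated ones. The label of a lower dose may explain it: replicate 1 correlated with the means of the vehicle (0.984), 21 mg/kg (0.983) and 27 mg/kg (0.97) animals by up to 0.043 more than with its own group (0.941). Animals may also have differed in how far they responded, and this cannot be told apart from a wrong label, since the score of replicate 1 along the change at 45 mg/kg, 0.08, lay apart from the 0.4, 0.87 and 1.02 of the others by less than the width of their range (at 27 mg/kg the scores were 0.74, 0.17, 0.16 and 0.93).

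Cyp2c11, Obp3, Car3, Stac3 and Dhrs7l1 fell at the top doses of both allyl alcohol and bromobenzene. Hepatocyte secreted proteins had medians of -0.43 (allyl alcohol) and -0.67 (bromobenzene), the least lowered of the 5 genes -3.41 and -5.54. A lower share of hepatocytes stays open in part, since the 5 were picked for large falls. A candidate explanation, open for the 5 genes as a set, is a move from the male towards the female pattern of sex-dependent liver genes: the mean of 2 other male-predominant genes, Cyp2c13 and Hsd3b5, fell at 2 of 2 top doses (-0.97 and -1.52, exact permutation p = 0.00794 each), and that of 4 female-predominant genes, Cyp2c12, A1bg, Cux2 and Cyp2a1, rose at 2 of 2 (0.69 and 0.89, exact permutation p = 0.00794 each, the smallest these animals allow). Single members carry these means with allyl alcohol, where Cux2 (1.74 ± 0.42) and Cyp2c13 (-1.42 ± 0.25) passed limma's test and Cyp2c12 (1.25 ± 0.49), A1bg (-0.20 ± 0.20), Cyp2a1 (-0.04 ± 0.18) and Hsd3b5 (-0.52 ± 0.20) did not, while with bromobenzene all but A1bg passed. These means also moved by less than the 5 genes, and under dexamethasone Car3 (-6.37 ± 0.72) and Stac3 (-5.42 ± 0.37) fell, before the median was taken off, with the male mean at 0.03 (exact permutation p = 0.675) and the female mean at -0.37 (0.0635), so these 2 genes can fall without such a move; lower food intake was not tested.

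Regrouping the arrays at random 100 times excluded chance for most counts. For genes changed, the real count and the highest of the other splits were 3 and 6, 9 and 5, and 3274 and 1168 at 27, 35 and 45 mg/kg allyl alcohol, 7 and 6, 108 and 8, 2366 and 1274, and 3581 and 2718 at rising doses of bromobenzene, 31 and 16, and 616 and 26 at 93 and 200 mg/kg carbon tetrachloride, 3081 and 1307, and 3315 and 1194 at 60 and 162 mg/kg 4,4'-methylenedianiline, and 4556 and 1392 under dexamethasone. In all of these 1 split of 100, the real one, was as large, except for 2 at 27 mg/kg. The real count was reached in 5 or more of 100 splits at 21 mg/kg allyl alcohol (1 and 1, 5 of 100), 20 mg/kg carbon tetrachloride (0 and 1, 100 of 100), 43 mg/kg carbon tetrachloride (1 and 10, 15 of 100, the highest other split, several times the real count, pointing to a structure of the animals that was not tested further) and 22 mg/kg 4,4'-methylenedianiline (0 and 1, 100 of 100).

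For lists called by camera, only the real split reached the count for 4,4'-methylenedianiline (18 and 17). More splits reached it for allyl alcohol (17 and 18, 7 of 100), bromobenzene (11 and 14, 19 of 100), carbon tetrachloride (11 and 14, 7 of 100) and dexamethasone (12 and 15, 9 of 100). Only the real split reached the count for the trends of allyl alcohol (3562 and 1), bromobenzene (4392 and 13), carbon tetrachloride (1027 and 2) and 4,4'-methylenedianiline (3386 and 1325), and for the vehicle groups (3899 and 41). It was excluded for all 10 pairs of responses: allyl alcohol with bromobenzene (2299 and 451), carbon tetrachloride (1327 and 63), 4,4'-methylenedianiline (563 and 135) and dexamethasone (4581 and 1689); bromobenzene with carbon tetrachloride (1488 and 330), 4,4'-methylenedianiline (1806 and 450) and dexamethasone (4236 and 1487); carbon tetrachloride with 4,4'-methylenedianiline (887 and 270) and dexamethasone (3323 and 837); and 4,4'-methylenedianiline with dexamethasone (5468 and 3842).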

How the results depend on the processing

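The offsets of 1 and 32 and the exact permutation of list means were chosen only after the result was seen. Of 6684 values of named genes under alternatives, 6361 kept their direction and side of the threshold, 277 no longer passed, 20 passed only there and 26 changed sign, all 26 of genes not called. The causes below were not tested, except where fewer arrays, other probe sets or a stricter threshold make the difference. With all 96 arrays in 1 fit limma called 0 genes at 21, 890 at 27 and 1698 at 35 mg/kg allyl alcohol, 13 at 124 mg/kg bromobenzene, and 0 at 43 and 6 at 93 mg/kg carbon tetrachloride; with the compared groups alone it called 0 at 27 and 5 at 35 mg/kg allyl alcohol, 0 at 124 and 1385 at 424 mg/kg bromobenzene, and 0 at 43 and 57 at 93 mg/kg carbon tetrachloride. At these doses 405, 1836, 984 and 735 genes (21 and 27 mg/kg allyl alcohol, 124 mg/kg bromobenzene, 43 mg/kg carbon tetrachloride) had an unadjusted p under 0.05 in limma's own-exposure fit. At 35 mg/kg allyl alcohol the count was 34 with the stricter filter on low values, 30 with array medians set equal, 22 with eBayes with trend and robust and 2535 with array weights; at 27 mg/kg it was 7 with the stricter filter. No filter on low values gave 20 genes at 93 mg/kg carbon tetrachloride; an offset of 1 gave 14 there and 0 at 124 mg/kg bromobenzene. Quantile normalization gave 2 genes at 43 mg/kg carbon tetrachloride.

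A minimum 2-fold change left 1003 genes at the top dose of allyl alcohol, 37, 289 and 630 at 229, 424 and 785 mg/kg bromobenzene, 0, 11 and 143 at 43, 93 and 200 mg/kg carbon tetrachloride, 590 and 606 at 60 and 162 mg/kg 4,4'-methylenedianiline and 711 under dexamethasone. For the responses it left 898, 492, 252 and 1944 genes for allyl alcohol with bromobenzene, carbon tetrachloride, 4,4'-methylenedianiline and dexamethasone, 447, 670 and 1503 for bromobenzene with the last 3, 320 and 1010 for carbon tetrachloride with the last 2, and 1535 for 4,4'-methylenedianiline with dexamethasone. All probe sets gave 5836 at 785 mg/kg bromobenzene, 2 and 14 at 43 and 93 mg/kg carbon tetrachloride, 5009 at 162 mg/kg 4,4'-methylenedianiline, 7417 under dexamethasone, trends of 5567 (allyl alcohol) and 7236 (bromobenzene), and 7307, 7227, 5163 and 9302 for allyl alcohol, bromobenzene, carbon tetrachloride and 4,4'-methylenedianiline with dexamethasone. An adjusted p under 0.01 gave trends of 1901 (allyl alcohol), 481 (carbon tetrachloride) and 1980 (4,4'-methylenedianiline) and 2067 genes between vehicle groups, which were 2386 with array medians set equal and 2171 after quantile normalization. Array weights gave 894 genes for allyl alcohol with 4,4'-methylenedianiline.

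At top doses camera with estimated correlation called 2 lists for bromobenzene and 0 for others. It called 1 each at 229 and 424 mg/kg bromobenzene and 93 mg/kg carbon tetrachloride. Exact permutation passed 0 for carbon tetrachloride, where 1 alone cannot pass. Spearman's rho was 0.392, 0.451, 0.624 and -0.036 for allyl alcohol with bromobenzene, carbon tetrachloride, 4,4'-methylenedianiline and dexamethasone, 0.434 and 0.131 for bromobenzene with the last 2, and 0.034 for 4,4'-methylenedianiline with dexamethasone; the stricter filter gave r = 0.477 (allyl alcohol with bromobenzene) and 0.737 (with 4,4'-methylenedianiline). With array medians set equal Tat was at -0.02 (bromobenzene) and -0.05 (4,4'-methylenedianiline), Col1a1 at -0.04 (carbon tetrachloride), Gpc3 at -0.1 (45 mg/kg allyl alcohol) and Cyp26b1 at -0.07 (60 mg/kg 4,4'-methylenedianiline), and after quantile normalization Cyp2a1 was at 0.05 (45 mg/kg allyl alcohol), all changes of sign. The replicate number as a block gave 2 genes at 43 and 58 at 93 mg/kg carbon tetrachloride and moved no other count by over 1.5 times; the animals share only a number, since deviations of same-numbered animals correlated between -0.14 and 0.21, and all pairs exceeded 0.1 in 0 of 16 comparisons.

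Leaving out 1 animal gave 0 to 111 genes at 27, 2 to 1629 at 35 and 2122 to 3649 at 45 mg/kg allyl alcohol, 1 to 15 at 124 and 60 to 124 at 229 mg/kg bromobenzene, 1 to 3 at 43, 8 to 32 at 93 and 355 to 598 at 200 mg/kg carbon tetrachloride, 703 to 1810 and 338 to 856 for allyl alcohol with carbon tetrachloride and with 4,4'-methylenedianiline, and 5 to 11 lists for carbon tetrachloride. Gene counts stayed at 0 at 20 mg/kg carbon tetrachloride and 22 mg/kg 4,4'-methylenedianiline. Of genes not called, some changed sign when 1 animal was left out: Lcn2 (-0.38 to 0.9) and Tat (-0.07 to 0.28) with bromobenzene, Col1a1 with carbon tetrachloride (-0.03 to 0.18), Afp (-0.22 to 0.05), Gpc3 (-0.34 to 0.41), A1bg (-0.3 to 0.03) and Cyp2a1 (-0.27 to 0.13) with allyl alcohol, Cyp7a1 (-0.53 to 0.21), Tat (-0.03 to 0.25) and, at 60 mg/kg, Cyp26b1 (-0.05 to 0.25) with 4,4'-methylenedianiline, and Krt19 (-0.08 to 0.15) and Cyp7a1 (-0.01 to 0.71) under dexamethasone before the median was taken off.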

Other observations

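The lists of MHC class II and fetal liver genes and the retinoic acid hydroxylase genes were chosen only after their values were seen. Of 8 MHC class II genes, which act in antigen presentation, 5 fell and 1 rose under dexamethasone, with RT1-Da at -3.9 ± 0.23, RT1-Ba at -3.81 ± 0.26 and the invariant chain gene Cd74 at -3.8 ± 0.21 lower and RT1-DMa at 2.58 ± 0.19 higher, before the all-gene median of -0.19 was taken off. At 162 mg/kg 4,4'-methylenedianiline 7 of 8 rose, with RT1-DMa, higher in both, at 1.62 ± 0.19, RT1-Da at 1.54 ± 0.23 and Cd74 at 1.26 ± 0.21. The mean of the list differed from the vehicle by -1.67 and 1.16 (n = 5 each), and the difference between these was not tested. Macrophage markers (14 of 18) fell under dexamethasone as well, and macrophage (11 of 18) and lymphocyte markers (8 of 12) rose at 162 mg/kg 4,4'-methylenedianiline. No p is given for this list or the next, as both were chosen after these values were seen.

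Of 6 genes of the fetal liver, 4 rose at 45 mg/kg allyl alcohol, with H19 at 4.39 ± 0.99, the pyruvate kinase gene Pkm at 2.44 ± 0.45, the hexokinase gene Hk2 at 1.41 ± 0.28 and Dlk1 at 0.55 ± 0.18, and Afp (-0.05 ± 0.2) and Gpc3 (0.15 ± 0.34) did not pass limma's test. The list mean was higher by 1.48. It differed from the vehicle by 0.55 and 0.40 at 60 and 162 mg/kg 4,4'-methylenedianiline, where 3 of 6 rose and 1 fell at each dose, by -0.08 at the top doses of bromobenzene and of carbon tetrachloride, and by -0.31 under dexamethasone before the median was taken off. Differences between toxicants were not tested for the list. Macrophage markers (15 of 18) and extracellular matrix genes (17 of 24) rose at 45 mg/kg allyl alcohol as well. The retinoic acid hydroxylase gene Cyp26b1 rose by 2.64 ± 0.37 at 162 mg/kg 4,4'-methylenedianiline.

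Sex-dependent genes were also measured at the other top doses. The mean of the 2 male-predominant genes differed from the vehicle by -0.26 (exact permutation p = 0.0317) with carbon tetrachloride, -0.82 (0.00794) with 4,4'-methylenedianiline and 0.03 (0.675) with dexamethasone, and that of the 4 female-predominant genes by 0.48 (0.135), 0.99 (0.0238) and -0.37 (0.0635), the dexamethasone values before the all-gene median of -0.19 was taken off.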
